A study of Mus musculus with 4 samples.

How the data were processed

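Small RNA was sequenced on the Solexa platform from 4 mouse cell populations of the C57BL/6J strain, with 1 library per population and no replicates. Per the labels' protocols, haematopoietic stem cells (HSC) were sorted from bone marrow as c-Kit positive, Sca1 positive, lineage negative cells. Immature dendritic cells (imDC) were bone marrow cells grown for 6 days with 10 ng/mL GM-CSF and 1 ng/mL IL-4. Mature dendritic cells (maDC) also received 10 ng/mL LPS from day 4 and were selected on CD11c beads at day 8. Regulatory dendritic cells (DCreg) were maDC kept for at least 7 days on a layer of endothelial-like splenic stromal cells and then selected on CD11c beads. RNA was isolated with the mirVana kit, gel purified to small RNA of 18 to 30 nt, ligated to adaptors and amplified for 12 cycles, per the labels.

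The series table gives a score per mature miRNA and hairpin, which the authors deposited as whole numbers that the file header calls normalised counts; how they were normalised is not given in the sources used here. Per the labels, reads matching rRNA, tRNA, mRNA, snRNA and snoRNA were filtered out and the clean reads were compared with miRBase release 19. The aligner, the mismatches allowed and the treatment of reads with several matches are not given in the sources used here. The columns sum to 4226458 for HSC, 5251069 for imDC, 4475569 for maDC and 2725948 for DCreg, so they were not scaled to a common total. The design fixed before the data were examined assumed read counts; because the values are a normalised score, no count model was used on them. Values were summed over the hairpins of each of 1078 mature miRNAs (715 hairpins, 1195 entries), and scaled to a column total of 1000000, so that levels are in parts per 1000000 (ppm).

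Each library also has a deposited list of unique sequences with copy numbers, as counts of reads. These lists hold 6277096 reads for HSC, 6554086 for imDC, 6572858 for maDC and 4904897 for DCreg, between 16 and 39 nt long, so they also hold reads outside the size range of the gel purification. They may be part of each library, as the sources used here do not say whether every read was deposited. They still hold reads of a class named as filtered out: a sequence matching Rnu3b snoRNA genes had 11496 copies in DCreg. Reads were recounted with an exact match to the mature sequences in the series table: at least 16 nt, a 5' end within 2 nt of the annotated one and at most 5 unmatched bases at the 3' end, the longest match being taken and reads with several equally good matches divided equally. This placed 82.8% of HSC, 80.4% of imDC, 84.0% of maDC and 80.2% of DCreg reads. Recounted values were scaled to a recounted total of 1000000.

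With 1 library per cell type there is no test and no p-value, and each difference has no replicate check. A miRNA was called different when its ratio, with a pseudocount of 0.5 on the deposited values, was at least 2-fold and it reached 100 ppm in 1 of the 2 libraries compared. Log2 ratios, list medians and the folds of enriched miRNAs over the next library include that pseudocount, and the other folds are plain ratios of the scaled deposited values. Beside them stand recounted folds with exact conditional 95% intervals (Clopper-Pearson). PCR reads without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only. The floor for a value of 0 is 3 counts, or 3 units of the deposited score. For the number of miRNAs detected, the whole-number scores were thinned to the smallest column total as if they were reads, although their normalisation is unknown. No fold of a single miRNA is given where both libraries are at or under the floor. List medians, however, include every member with a value above 0 in either library.

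The miRNAs named in the text follow a rule fixed before the data were examined: the 10 with the largest ratio in each direction of each comparison, the 10 most abundant of each library, up to 5 enriched miRNAs per library, and members of 13 fixed lists that reach 100 ppm, of which about 20 to 30 are named per comparison; of sequences given to no miRNA, the 5 with most copies per library. A miRNA was called enriched in a library at 4-fold or more above the highest of the other 3. The lists cover miRNAs associated with HSC and progenitors, myeloid cells, Toll-like receptor (TLR) and NF-kB responses, dendritic cell (DC) function, lymphoid, erythroid, endothelial and stromal or mesenchymal cells, and tissues outside the sample, and the miR-30, let-7, miR-17-92 and Dlk1-Dio3 groups. The miR-30 list was chosen because later work by the study's authors concerned miR-30b, so its counts are not independent evidence. miR-152-3p is on both the DC function and the stromal lists, let-7e-5p on both the HSC and the let-7 lists, and miR-126 on both the HSC and the endothelial lists. A list's median log2 ratio is given with its percentile among 10000 random lists of the same size, as a description of these libraries. Random members were drawn independently from 10 bins of mean expression. Several lists hold both arms of a hairpin or hairpins of the same cluster, which can vary together. Their percentiles can thus be more extreme than those of unrelated members. Medians at a percentile under 2.5 or over 97.5 are set apart in the text.

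Alternatives fixed before the data were examined were scaling by the trimmed mean of M-values, by median-of-ratios, by all reads of the library and by the total without the 5 most abundant miRNAs; a filter of 10 ppm or none; a pseudocount of 5; a 4-fold rule; counting recounted reads or only reads identical to the mature sequence; and summing miRNAs with the same bases 2 to 8. For the other results they were random lists not matched on expression, list members at 10 ppm, other fold rules and filters for enriched miRNAs, no thinning or a minimum of 10 for detection, the 5 most abundant miRNAs, Pearson's r, correlation at 100 ppm, and lengths over sequences with 10 copies or over unique sequences. Alternatives chosen after seeing the data were leaving out miRNAs with few recounted reads, leaving out the lists of other cell types, and recounted reads, median-of-ratios and the total without 5 miRNAs for the lists.

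Scripts were tested on simulated data. The recount came within 10% of the true value for 97.2% of sequences of 20 nt or longer. With scaling by total, 4-fold changes were called in 100% of 45 miRNAs for imDC against HSC, 35 for maDC against imDC, 33 for DCreg against maDC and 42 for DCreg against imDC. Of unchanged miRNAs, 0%, 5.19%, 1.64% and 0% were called in the same order of comparisons. These rates check the scripts only. Without replicates the spread between cultures and library preparations is unknown, so the rates are not false-call rates for real cultures.

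Recounted reads fell under 30% of the deposited value for 38 of the 278 miRNAs with a deposited sum of at least 300, which hold 5.57% of the deposited values (7.94% in HSC, 5.18% in imDC, 5.14% in maDC and 3.34% in DCreg). Of the 38, 5 are the antisense strand of another miRNA over at least 16 nt: miR-1b-5p, miR-3074-5p, miR-3107-3p, miR-374c-3p and miR-466f-3p. They were kept in the counts of different and enriched miRNAs, which are counts of names. Hairpin positions come from GENCODE release M21 on GRCm38 and are those whose transcript holds the mature sequence. The software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.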

Results

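The data are small RNA profiles of 4 stages of mouse dendritic cell (DC) development: sorted bone marrow haematopoietic stem cells (HSC), cytokine-grown immature DC (imDC), LPS-matured DC (maDC) and regulatory DC (DCreg), which the design describes as making IL-10 and nitric oxide. There was 1 library per cell type. The deposited miRNA values summed to between 2725948 (DCreg) and 5251069 (imDC) per library. The question the design poses is how the miRNA set differs between a progenitor, the immature and mature DC grown from bone marrow, and the regulatory DC that arise from mature DC on stroma.

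Members of the let-7 family and miR-140-3p were among the 10 most abundant miRNAs of every library, and miR-21-5p and miR-29a-3p among those of the 3 DC libraries. The 10 most abundant miRNAs held 61.8% of the deposited values in HSC, 61.9% in imDC, 70.1% in maDC and 78.3% in DCreg. Of recounted reads the 10 most abundant held 75.8%, 68.5%, 83.2% and 88.1% in the same order. By the deposited values the leading miRNA was let-7f-5p in HSC (97889 ppm, parts per 1000000 of the library's deposited total) and maDC (116094). It was miR-21-5p in imDC (140653) and miR-140-3p in DCreg (151631). The recount gave other leaders in these 2 libraries. Of recounted imDC reads let-7f-5p held 13.98% and miR-21-5p 10.96%. Of recounted DCreg reads let-7c-5p held 25.3% and miR-140-3p 7.86%. Also among the 10 were miR-191-5p and miR-25-3p in HSC, and miR-146b-5p in the 3 DC libraries. The recount assigned no reads to miR-191-5p. The let-7 family held 45.6% of HSC, 28.9% of imDC, 47.6% of maDC and 51.7% of DCreg values, and 68.0%, 48.6%, 72.9% and 74.7% of recounted reads. After thinning of the deposited values as if they were reads to the smallest total, 836 miRNAs had a value of at least 1 in HSC, 826 in imDC, 758 in maDC and 749 in DCreg. Spearman's rho across 392 miRNAs, which are not independent replicates, was 0.891 between imDC and maDC (bootstrap interval 0.863 to 0.915), 0.837 between maDC and DCreg, 0.747 between imDC and DCreg, 0.701 between HSC and imDC, 0.620 between HSC and maDC and 0.617 between HSC and DCreg. Reads of 21 to 23 nt made up 82.0% of HSC, 76.5% of imDC, 84.6% of maDC and 79.6% of DCreg reads (exact 95% interval for DCreg 79.6% to 79.7%), and 22 nt was the commonest length in all 4 libraries.

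**Figure D1:**
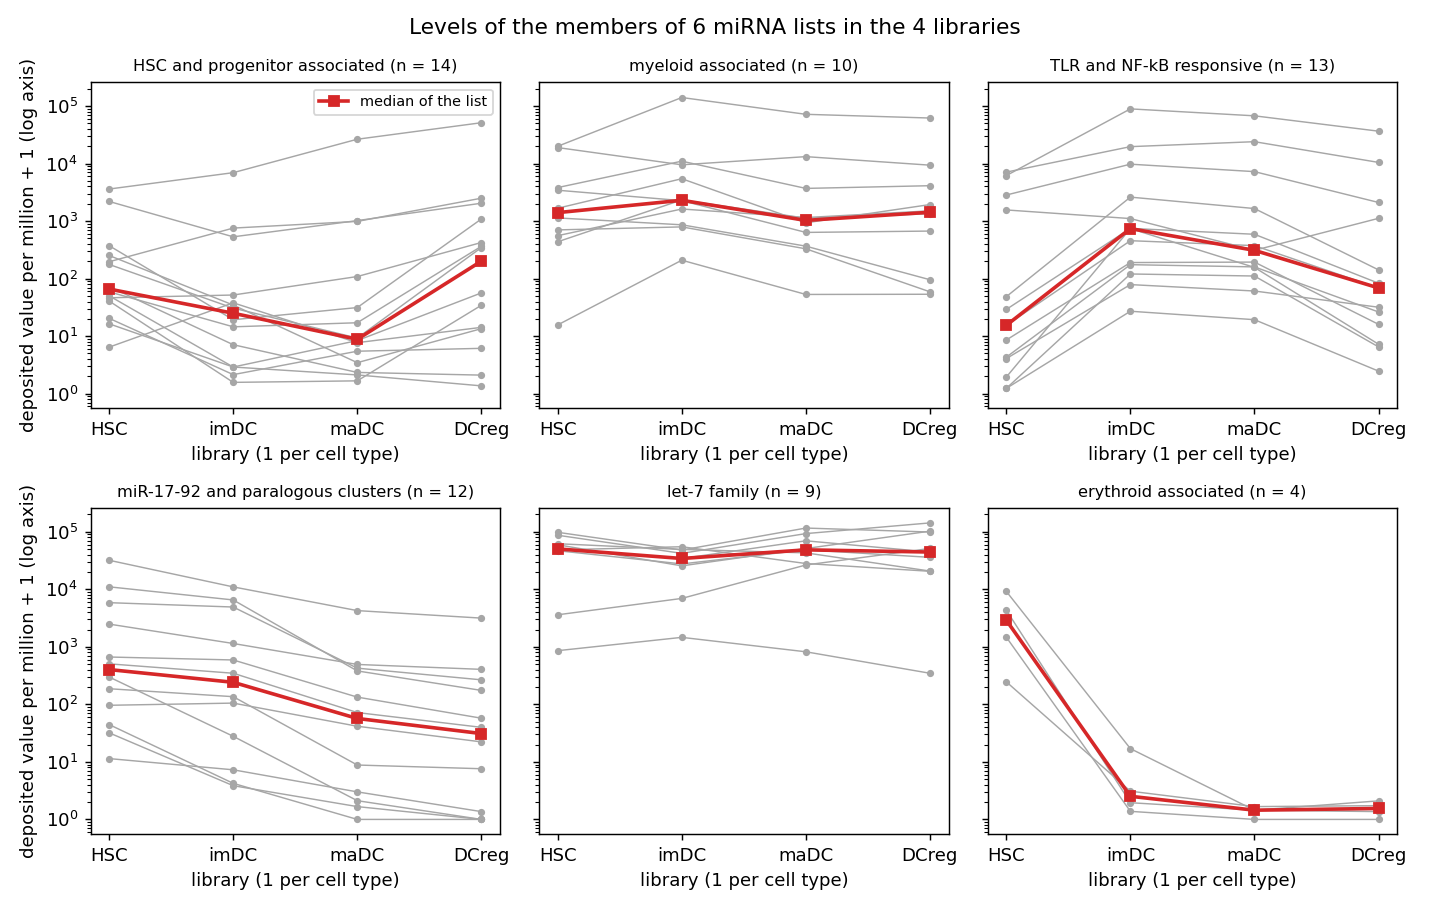
Deposited values in ppm plus 1 (log axis) of the members of 6 miRNA lists in the 4 libraries; each grey line is a miRNA and the red line is the median of the list. The median of the TLR and NF-kB list was 14.4 ppm in HSC, 739 in imDC, 309 in maDC and 67.9 in DCreg. That of the HSC and progenitor list was 64.8, 24.0, 7.82 and 200.1 in the same order. For maDC against imDC the median log2 ratio of the TLR and NF-kB list changed direction with the scaling. That of the HSC and progenitor list was 0.32, opposite in direction to its median level.

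Immature DC were first compared with HSC, the bone marrow progenitors. The imDC library held far more of the miRNAs tied to inflammatory signalling and far less of the erythroid set, and 6 of 10 myeloid miRNAs were higher in it. miR-155-5p, a regulator of DC and lymphocyte activation, was 54.9-fold higher in imDC (recount 73.8-fold, interval 62.9 to 87.0). miR-146b-5p, which targets adaptors of TLR signalling, was 14.4-fold higher (recount 17.0-fold, 16.6 to 17.4) and reached 89225 ppm, against 28909 ppm of recounted reads. miR-144-3p and miR-451, made from an erythroid gene cluster that GATA1 controls, were 4546-fold and 574-fold lower (recount 3563-fold, 1391 to 13077, and 433-fold, 341 to 557). Of 187 miRNAs tested, 49 were at least 2-fold higher in imDC and 53 lower (51 sequences, as 2 pairs of names share one).

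Of the 11 tested members of the TLR and NF-kB list, 10 were higher in imDC and none was lower; the list's median log2 ratio was 4.72, percentile 100. miR-9-5p, which is induced by NF-kB in myeloid cells, was 781-fold higher (recount 1386-fold, 672 to 3448), at 739 ppm in imDC and 0.946 in HSC. Its other arm, miR-9-3p, was 363-fold higher by recount (141 to 1333). miR-212-3p, miR-212-5p and miR-132-3p, which share a primary transcript, were 52.4-, 25.0- and 31.5-fold higher, and miR-147-3p, induced by TLR ligands in macrophages, was 26.5-fold higher. miR-222-3p and miR-221-3p were 3.44- and 2.77-fold higher. miR-146a-5p was the member under 2-fold, at 1105 ppm in imDC and 1561 in HSC. Of the 10 tested myeloid miRNAs, 6 were higher (median 1.53, percentile 99.8), among them miR-34a-5p (14.2-fold, recount 24.4-fold), miR-21-5p (7.04-fold), miR-22-3p (5.35-fold) and miR-27a-3p (3.26-fold). miR-223-3p, the granulocyte and monocyte miRNA, stood at 3438 ppm in HSC and 2264 in imDC, and miR-142-5p and miR-142-3p, of the blood lineages, at 18959 and 1133 ppm in HSC and 9513 and 861 in imDC. Outside the lists, miR-210-3p, a target of hypoxia-inducible factor, was 33.0-fold higher and miR-34c-5p 29.9-fold higher.

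The HSC and progenitor list lay lower in imDC (4 of 6 tested lower, 1 higher; median -2.73, percentile 0). miR-196b-5p, from a Hox gene cluster, was 7.45-fold lower, miR-99a-5p 5.90-fold and miR-10a-5p 4.13-fold, while miR-99b-5p was 3.86-fold higher. All 4 erythroid miRNAs were lower (median -10.37, percentile 0), miR-144-5p by 2480-fold in the recount (686 to 20487) and miR-486-5p by 117-fold. Markers of further cell types were also more abundant in HSC: miR-150-5p of mature lymphocytes was 53.3-fold lower in imDC, the stromal miRNAs miR-143-3p and miR-199a-3p 29.8- and 13.4-fold lower, and the muscle miRNAs miR-1a-3p and miR-206-3p 680- and 29.9-fold lower. The stromal list had a median of -3.74 (percentile 0, with 3 of 4 tested lower, of which miR-199a-3p and miR-199b-3p share a mature sequence). The endothelial list (both arms of miR-126, each under 100 ppm) had a median of -4.08 (percentile 2), and the Dlk1-Dio3 list, with no member at 100 ppm, -1.90 (percentile 0.05; -0.68 with zeros at the floor). In the miR-30 family 3 of 7 tested were lower and none higher (median -0.80), a list chosen for the study's known follow-up. Medians of the let-7 (-0.55), miR-17-92 (-0.74), lymphoid (-0.79), DC function (0.38) and outside tissue (0.41) lists lay inside the central range.

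The split between higher and lower depended on the scaling: it was 58 and 35 with the trimmed mean of M-values and 55 and 34 with all reads as the total, and these moved the median of tested miRNAs by 0.21 and 0.25 from -0.12. Recounted reads gave 55 higher and 28 lower; of the called miRNAs with enough recounted reads, 95 of 97 kept their direction, miR-1b-5p (listed 526-fold lower) being among the exceptions.

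Maturation was examined by comparing maDC with imDC, which differ in LPS exposure, in days of culture and in the CD11c selection. Their reads given to no miRNA also differ. The commonest such sequence in HSC and imDC, of 17 nt, had 22595 and 28391 copies there, 870 in maDC and 1907 in DCreg. A sequence of 20 nt, rank 5 in HSC, had 15005, 7365, 139 and 290 copies in the same order. Others of the commonest went the other way. Whether the library preparation differed was not tested, and with a single library per cell type it cannot be told apart from maturation. The maDC library held less of most miRNAs at 100 ppm, with 15 of 160 at least 2-fold higher and 72 lower. The miR-17-92 group, a set of clusters that promote proliferation, was lower throughout: all 8 tested members were at least 2-fold lower (median -2.22, percentile 0; -2.12 with zeros at the floor). let-7e-5p was 3.81-fold higher (recount 3.72-fold, 3.67 to 3.78). With scaling by total, no tested member of the TLR and NF-kB list was at least 2-fold higher in maDC.

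Within the miR-17-92 group, miR-92a-3p was 17.2-fold lower (recount 31.9-fold, 30.1 to 33.8), miR-19b-3p 17.3-fold, miR-93-5p 11.6-fold, miR-20a-5p 4.88-fold and miR-17-5p 4.45-fold. miR-15b-3p was 9.52-fold lower. Of the 10 myeloid miRNAs, 7 were lower and none higher (median -1.25, percentile 6.34): miR-27a-3p 5.85-fold (recount 11.4-fold), miR-34a-5p 3.99-fold, miR-223-3p 3.57-fold and miR-23a-3p 2.98-fold. miR-27b-3p, of the same seed family as miR-27a-3p, was 11.2-fold lower (recount 19.6-fold) and miR-378-3p 4.94-fold. All 5 tested miR-30 members were lower, miR-30e-3p by 12.2-fold and miR-30b-5p by 4.52-fold (median -1.61, percentile 7.07). miR-652-3p, miR-1965 and miR-374-5p were 10.1-, 9.89- and 8.66-fold lower.

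Of 9 let-7 members, 5 were higher and none lower (median 1.00, percentile 99.9); let-7f-5p was 2.41-fold and let-7b-5p 2.21-fold higher (recount 1.94- and 1.75-fold). miR-221-5p was 2.88-fold higher, miR-877-5p 2.43-fold and miR-298-5p 2.28-fold. Of the miRNAs higher in maDC, let-7e-5p and miR-221-5p were at least 2-fold higher at 100 ppm or more in the recount (miR-877-5p 1.79-fold, miR-298-5p 1.72-fold). The stromal list had a median of 1.23 (percentile 100, recounted median 0.95 over 5 members), with miR-199a-3p 2.57-fold higher (recount 1.94-fold). The other tested member, miR-152-3p, stood at 826 ppm in maDC and 857 in imDC. That median includes miR-199a-5p, miR-199b-5p and miR-218-5p, under the floor in both libraries. It also counts the shared sequence of miR-199a-3p and miR-199b-3p under both names. The HSC and progenitor list had a median of 0.32 (percentile 99.1; 2 of 4 tested higher), which turned to -0.068 in recounted reads of all members with a read and -0.14 over the 11 members above the floor; miR-125a-5p was 2.12-fold higher (recount 1.73-fold). In the TLR and NF-kB list 2 of 11 were lower, miR-9-5p by 4.76-fold and miR-146a-5p by 3.57-fold, and miR-155-5p stood at 1651 ppm in maDC and 2609 in imDC. That list's median of -0.37 turned to 0.18 with the trimmed mean of M-values and 0.33 with median-of-ratios. Medians of the lymphoid (-0.80), erythroid (-1.79), endothelial (-1.40), Dlk1-Dio3 (0.23), outside tissue (-0.67) and DC function (-0.56) lists lay inside the central range, the last turning to 0.14, the outside tissue list to 0.04 (both with median-of-ratios) and the Dlk1-Dio3 list to -0.0041 with all reads as the total. miR-5126, miR-1895 and miR-5103 were listed 32.1-, 11.8- and 2.53-fold higher, but have few or no recounted reads: miR-5126 was 3.50-fold higher in the recount (2.27 to 5.57), miR-1895 had none and miR-5103 was 0.220-fold (0.0402 to 0.801).

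The excess of lower over higher miRNAs depended on the scaling, being 27 higher and 43 lower with the trimmed mean of M-values and 31 and 32 with median-of-ratios, which moved the median of -0.88 by 0.55 and 0.70; all reads as the total moved it by -0.23 and leaving out the 5 most abundant miRNAs by 0.24. Recounted reads gave 2 higher and 78 lower.

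Regulatory DC were compared with the maDC from which they were derived. The DCreg library held less of most tested inflammatory miRNAs and more of most tested members of the HSC and progenitor list. That name is of a fixed list and does not mean a level near that of HSC. miR-99b-5p, let-7e-5p and miR-125a-5p were lowest in HSC of all libraries (let-7e-5p 3606 ppm in HSC, 51264 in DCreg). Of the tested members only miR-10a-5p stood higher in HSC (2193 ppm) than in DCreg (2042). miR-155-5p was 11.7-fold lower (recount 12.7-fold, 11.4 to 14.2), at 141 ppm. miR-31-5p was 49.9-fold higher (recount 85.6-fold, 66.3 to 112), and miR-125b-5p, which sustains haematopoietic stem cells, 22.6-fold higher (recount 24.9-fold, 20.2 to 31.0). Of 138 miRNAs tested, 28 were at least 2-fold higher in DCreg and 39 lower.

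Of 11 tested members of the TLR and NF-kB list, 9 were lower and 1 higher (median -2.64, percentile 0). miR-9-5p was 24.9-fold lower, miR-9-3p 21.8-fold in the recount, miR-212-5p 12.8-fold, miR-147-3p 7.17-fold, miR-212-3p 6.28-fold, miR-132-3p 5.50-fold and miR-222-3p 3.44-fold. miR-146a-5p, a brake on TLR signalling, went the other way and was 3.61-fold higher (recount 3.08-fold, 2.88 to 3.30). Outside this list miR-296-3p was 14.9-fold lower, and of the myeloid miRNAs miR-223-5p was 5.67-fold and miR-142-3p 3.86-fold lower while miR-27a-3p was 2.08-fold higher (recount 1.98-fold). miR-191-5p was listed 3.85-fold lower and miR-5126 36.8-fold lower; the former had no recounted reads and the latter was 3.92-fold lower in the recount.

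Of 7 tested HSC and progenitor miRNAs, 6 were higher and none lower (median 1.66, percentile 99.98). miR-99a-5p, encoded in an intron of Mir99ahg (GRCm38 chromosome 16, 77598936 to 77599000, plus strand), which also hosts 1 of the 2 hairpins of miR-125b, was 41.7-fold higher, miR-125a-5p 3.93-fold, miR-99b-5p 2.53-fold and miR-10a-5p 2.01-fold (recount 1.91-fold); miR-130a-3p was listed 35.7-fold higher but had no recounted reads. The Mir31 hairpin lies on chromosome 4 (88910557 to 88910662, minus strand, GRCm38) in an exon of the long non-coding gene AL805899.1. miR-129-5p was 120-fold higher (recount 108-fold, 49.3 to 296), miR-182-5p 11.6-fold, miR-30a-5p 11.2-fold and miR-322-5p 6.72-fold. miR-129-2-3p was listed at 303 ppm against 2.90, with 1 recounted read in DCreg. Of the miR-30 list 1 of 3 tested was higher and none lower (median 0.55); miR-30b-5p, under the level for testing, stood at 50.3 ppm in DCreg and 24.8 in maDC. Markers of other cell types went both ways: the stromal miR-143-3p and miR-152-3p were 3.80- and 2.74-fold higher, the muscle miR-1a-3p and miR-206-3p 9.06- and 4.14-fold higher, and the lymphoid miR-181b-5p and miR-342-5p 3.95- and 3.03-fold lower, while the endothelial miR-126-3p had 1 recounted read in DCreg and 2 in maDC.

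The stromal list had a median of -0.022 (0.72 with zeros at the floor). The other medians inside the central range were those of the myeloid (0.05), DC function (-0.14), let-7 (-0.43), miR-17-92 (-0.93), lymphoid (-0.87), erythroid (0.23), endothelial (-0.67), Dlk1-Dio3 (0.94) and outside tissue (-0.87) lists. Every erythroid member lay at or under the floor in both libraries, so nothing is read from that list's median. Scaling turned 4 medians near 0, of which the erythroid one rests on members at or under the floor. All reads as the total gave -0.25 for the myeloid and -0.06 for the erythroid list. Leaving out the 5 most abundant miRNAs gave 0.25 for the DC function and 0.37 for the stromal list, which was also 0.08 with the trimmed mean of M-values. The split was 18 higher and 41 lower with all reads as the total and 45 and 24 without the 5 most abundant miRNAs, with shifts of -0.29 and 0.40 in the median of -0.34; the trimmed mean of M-values shifted it by 0.10. In the recount all 59 called miRNAs with enough reads kept their direction.

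DCreg were last compared with imDC, which had met neither LPS nor stroma. The DCreg and imDC libraries also differ in days of culture, in the CD11c selection and in the unassigned sequences described for maDC against imDC. DCreg held less of the miR-17-92 group, of the TLR and NF-kB miRNAs and of most others. It held more of the tested members of the HSC and progenitor list. miR-92a-3p was 37.6-fold lower (recount 64.1-fold, 58.4 to 70.6), miR-155-5p 18.5-fold lower (recount 24.9-fold, 22.4 to 27.8) and miR-31-5p 138-fold higher (recount 111-fold, 82.8 to 153). Of 168 miRNAs tested, 27 were at least 2-fold higher in DCreg and 94 lower.

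All 8 tested members of the miR-17-92 group were lower (median -3.77, percentile 0; -3.27 with zeros at the floor), including miR-19b-3p (20.4-fold), miR-93-5p (18.5-fold), miR-17-5p (10.4-fold) and miR-20a-5p (8.91-fold). Of 11 TLR and NF-kB miRNAs 9 were lower and none higher (median -2.77, percentile 0.03), led by miR-9-5p (119-fold) and miR-9-3p (21.7-fold), with miR-212-5p 12.6-fold (recount 20.1-fold), miR-147-3p 9.07-fold (recount 15.6-fold) and miR-132-3p 6.71-fold lower; miR-146a-5p stood at 1115 ppm in DCreg and 1105 in imDC. Of 10 myeloid miRNAs 7 were lower and none higher (median -1.45), among them miR-223-5p (13.7-fold, recount 24.6-fold), miR-142-3p (9.09-fold) and miR-21-5p (2.27-fold). miR-27b-5p, miR-296-3p, miR-200c-3p and miR-15b-3p were 19.6-, 17.7-, 17.0- and 16.1-fold lower, miR-200c-3p by 29.1-fold in the recount. miR-148a-3p and miR-148b-3p, which restrain antigen presentation by DC, were 9.80- and 5.69-fold lower, whereas miR-152-3p of the same family was 2.64-fold higher (recount 1.84-fold).

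All 7 tested HSC and progenitor miRNAs were higher (median 2.49, percentile 100): miR-125b-5p 26.9-fold, miR-99a-5p 11.6-fold, miR-125a-5p 8.32-fold, let-7e-5p 7.38-fold, miR-10a-5p 3.84-fold, miR-99b-5p 3.31-fold, and miR-130a-3p, without recounted reads, 59.4-fold. Members under 100 ppm in both libraries went both ways. There miR-126-3p, miR-126-5p, miR-196b-5p and miR-193b-3p were lower in DCreg, while miR-100-5p, miR-10b-5p and miR-196a-5p were higher. miR-129-5p was 62.7-fold higher and miR-322-3p 7.76-fold, and miR-129-2-3p was listed at 303 ppm against 0.190. The let-7 family went both ways, 4 members being higher and 3 lower (median 0.38, percentile 99.2; -0.15 with all reads as the total and -0.0028 in recounted reads): let-7c-5p was 4.01-fold higher and let-7i-5p 2.67-fold lower. Both tested stromal miRNAs were higher (median 1.40, percentile 98.9), miR-143-3p by 12.0-fold, as was the muscle miR-1a-3p by 11.3-fold. The Dlk1-Dio3 list, with no member at 100 ppm, had a median of 0.85 (percentile 99.05; 1.86 with zeros at the floor), and in the recount 1 member lay above the floor, too few for a median. In the miR-30 list 3 of 5 tested were lower and 1 higher (median -0.93), with miR-30b-5p 2.23-fold lower and miR-30a-5p 3.66-fold higher. Medians of the lymphoid (-2.18), erythroid (-1.32), endothelial (-2.07), outside tissue (-1.25) and DC function (-0.37) lists lay inside the central range, the last turning to 0.28 with the trimmed mean of M-values, 0.34 with median-of-ratios and 0.26 without the 5 most abundant miRNAs.

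The lower miRNAs outnumbered the higher ones under every scaling tried, though less so with some: 37 higher and 62 lower with the trimmed mean of M-values, 37 and 58 with median-of-ratios, and 47 and 76 without the 5 most abundant miRNAs. These moved the median of -1.25 by 0.65, 0.72 and 0.63, and all reads as the total moved it by -0.53.

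**Figure D2:**
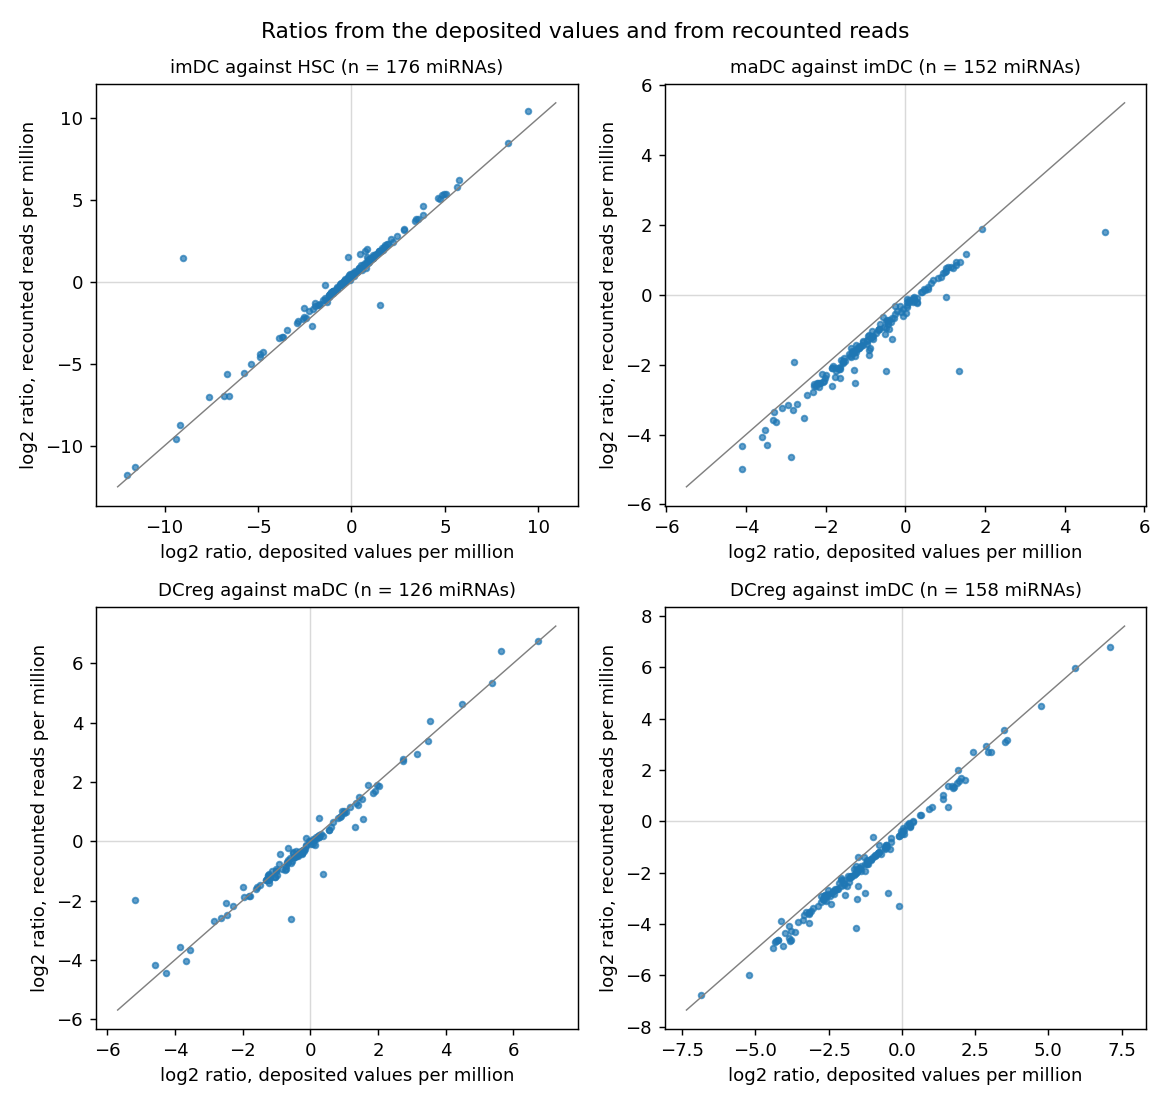
Log2 ratios per miRNA from the deposited values (x axis) and from recounted reads in ppm (y axis) for miRNAs at 100 ppm or more with recounted reads in both libraries of each comparison; the line marks equal ratios. Most points run along the line, shifted up in imDC against HSC and down in maDC against imDC and DCreg against imDC. Single points far from it include miR-1b-5p in imDC against HSC and miR-5126 in maDC against imDC.

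Across all 4 libraries 30 miRNAs were enriched in 1 library by the 4-fold rule: 23 in HSC, 1 in imDC, 1 in maDC and 5 in DCreg. The HSC set was led by miR-144-3p, miR-144-5p, miR-451 and miR-486-5p, with miR-3107-3p listed among them, and 20 of the 23 also met the rule in recounted reads. Because miR-486-5p and miR-3107-5p share a mature sequence, as do miR-199a-3p and miR-199b-3p, the 23 names stand for 21 sequences and the 20 for 18. The imDC miRNA was miR-9-5p (4.75-fold above maDC) and the maDC one was miR-5126, which did not meet the rule in recounted reads. The DCreg set was miR-129-2-3p, miR-31-5p (49.7-fold above maDC), miR-129-5p, miR-125b-5p (6.26-fold above HSC) and miR-182-5p (5.42-fold above imDC); 4 of the 5 met the rule in recounted reads, the exception being miR-129-2-3p.

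**Figure D3:**
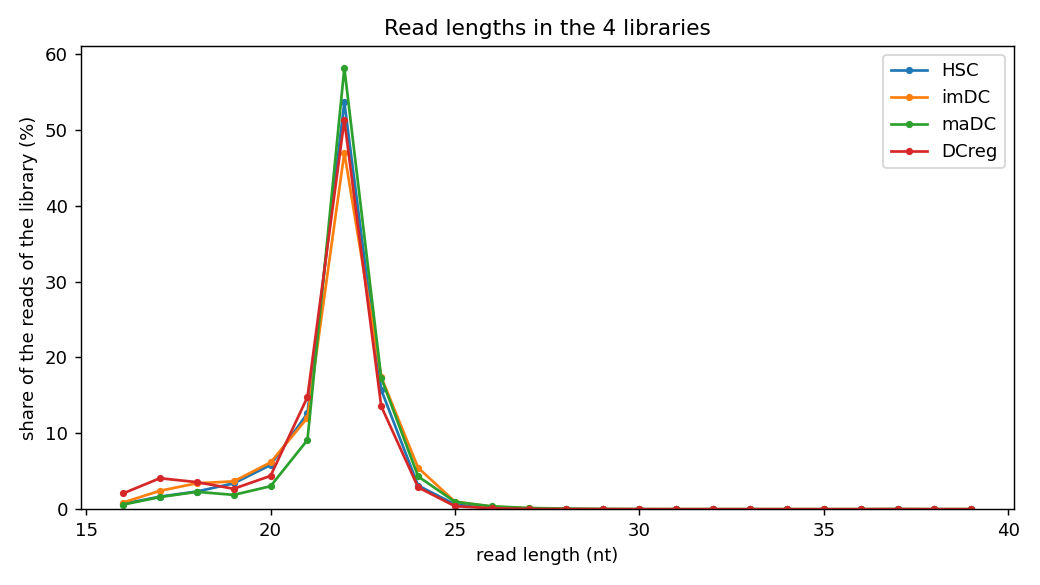
Share of the reads of each library (%, y axis) by read length (nt, x axis), 1 line per library. All 4 peak at 22 nt, with 47.0% of imDC and 58.1% of maDC reads at that length, and DCreg has the largest share under 18 nt (6.17%).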

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

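All tests in this part were chosen only after the results they bear on had been seen.

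Reads given to no miRNA play no part in the comparisons, and are given here because they hold a signal above the 3 counts that a count of 0 allows. Any common ending would pass that limit, so it shows no excess of CCA, the ending of mature tRNAs. Reads assigned to no miRNA and ending in CCA made up 2.97% of HSC, 2.88% of imDC, 1.75% of maDC and 3.08% of DCreg reads. CCA was the commonest 3-base ending of unassigned reads in HSC (17.3%), imDC (14.7%) and DCreg (15.5%), and came after GTT in maDC (10.99% against 11.9%). The sequence CCGTGGACGGTGTGAGGC had 15038 copies in maDC, 45 in HSC, 44 in imDC and 212 in DCreg, and was matched to no GENCODE transcript. The sequence CCACGAGGACGAGACGT had 11496 copies in DCreg and 77 in maDC, and matches the Rnu3b small nucleolar RNA genes.

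CCA-ending reads of 16 to 19 nt were 2.60-fold more common in DCreg than in maDC (2.58 to 2.62) and those of 20 nt and longer 2.40-fold less common (2.35 to 2.45; 0.283% of DCreg, 0.680% of maDC, 1.62% of imDC and 2.06% of HSC reads), so that the short ones made up 90.8% of CCA-ending reads in DCreg, 61.3% in maDC, 43.7% in imDC and 30.7% in HSC. A single abundant sequence is argued against, since without ACCGGGCGGAAACACCA the short reads were still 2.22-fold more common than in maDC (2.20 to 2.25). More short reads of every kind, miRNA reads included, is argued against for the difference from HSC and imDC. Of reads assigned to miRNAs, 16 to 19 nt made up 1.95% in DCreg, 3.64% in HSC and 4.54% in imDC. This put DCreg at 0.535 of the share in HSC (0.530 to 0.539). Against maDC (0.729%) that share was 2.67-fold higher in DCreg (2.64 to 2.701), and there the explanation stays open, since both shares do not put the 4 libraries in the same order and reads under 18 nt lie below the 18 to 30 nt range of the gel purification, where recovery is unknown. These shares cover only reads assigned to miRNAs, so RNA breakdown or size selection that raised short reads of other RNA is not excluded. Of all reads, those under 18 nt made up 6.17% in DCreg, 2.21% in maDC, 3.31% in imDC and 2.36% in HSC. The biological difference between the cell types also stays open and was not tested.

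The HSC library held erythroid and muscle miRNAs at levels far above imDC. Sharing of reads between similar or antisense names is argued against: in the recount the lowest of 6 such miRNAs, miR-206-3p, was still 20.9-fold above imDC (17.5 to 25.2). RNA from erythroid cells stays open and untested: that all 4 miRNAs on that list were at least 117-fold higher in HSC is the pattern itself. The lineage-negative gate is meant to remove mature erythroid cells, but how many remained was not measured here. For muscle RNA the values decide nothing: HSC had 384 recounted reads of miR-1a-3p per read of miR-133a-3p (343 to 432), whose ratio in muscle was not measured here. Expression in the stem cells themselves stays open and was not tested.

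The miRNAs enriched in DCreg were weighed against the authors' assignment of reads and against RNA from the stromal layer. Misassignment is argued against for 4 of the 5, the lowest being miR-182-5p at 6.51-fold in the recount (5.49 to 7.77), but stays open for miR-129-2-3p, of whose deposited sum the recount found 0.117%. Stromal cells that hold miR-126 at the level of the enriched miRNAs are argued against by its upper bound of 1.42 ppm in DCreg, where the lowest of the 4 stood at 117 ppm. Stromal cells with mesenchymal miRNAs could not be excluded: the list's median against maDC was -0.022, with 2 of 3 tested members at least 2-fold higher. The CD11c selection after co-culture is meant to remove stromal cells, but how many remained was not measured here. Stromal cells without miR-126, and a difference between the cell types, stay open.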

How the results depend on the processing

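Leaving out miRNAs with few recounted reads or the lists of other cell types, and for lists and enriched miRNAs recounted reads, median-of-ratios and the total without 5 miRNAs, were tests chosen after seeing the data. Of the settings tried on the results that answer a comparison, 57 left them within 1.5 times or within their counting error and 38 moved them. With a filter of 10 ppm the miRNAs at least 2-fold different numbered 198 (imDC against HSC), 186 (maDC against imDC), 157 (DCreg against maDC) and 250 (DCreg against imDC), in place of 102, 87, 67 and 121. With no filter they numbered 579, 560, 472 and 620, and at 4-fold 49, 31, 23 and 68, as these rules test more or accept fewer miRNAs by construction. Reads identical to the mature sequence gave 66 for imDC against HSC and 30 for DCreg against maDC; the cause was not tested. Enriched miRNAs went from 30 to 77 at 2-fold and 57 at 10 ppm, and those with a thinned deposited value of 10 or more were 427 in HSC, 422 in imDC, 371 in maDC and 379 in DCreg. The 5 most abundant miRNAs held 38.1%, 39.7%, 43.6% and 55.8% in the same order. Pearson's r was 0.788 (HSC and imDC), 0.739 (HSC and maDC), 0.733 (HSC and DCreg), 0.932 (imDC and maDC), 0.837 (imDC and DCreg) and 0.907 (maDC and DCreg). Reads of 21 to 23 nt made up 84.6%, 79.0%, 87.3% and 82.8% among sequences with at least 10 copies, and 43.7%, 42.2%, 40.004% and 32.2% of unique sequences. Of 395 settings on 80 named ratios, 386 kept at least 2-fold in the same direction and 2 turned, both in recounted reads: miR-1b-5p for imDC against HSC (log2 1.33) and miR-5103 for maDC against imDC (log2 -2.02). A further 188 settings moved the ratio without turning it, and 205 left it the same. The named ratios were chosen as the largest in each direction, so keeping 2-fold was likely beforehand and says little about smaller ratios. Named miRNAs lacking recounted reads in 1 or both libraries have no recounted ratio, so they could not turn there. Of 52 list medians 19 lay outside the central range. Those that turned were the HSC and progenitor list for maDC against imDC (-0.068 in recounted reads, -0.14 over the members above the floor) and, for DCreg against imDC, the let-7 list (-0.15 with all reads as the total, -0.0028 in recounted reads). The cause was not tested for any that turned. The Dlk1-Dio3 list for DCreg against imDC came to -1.16 over recounted members with any read, nearly all at or under the floor, and to 4.33 for the 1 member above it, so a turn is not shown. With 1 library per cell type, depth limits counting error only, and the spread between cultures is unknown.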

Other observations

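The miRNAs of 1 cluster on chromosome 17 stood in the same order across the libraries. miR-99b-5p, let-7e-5p and miR-125a-5p are encoded within Spaca6 on the plus strand (GRCm38, Mir99b at 17830188 to 17830257, Mirlet7e at 17830352 to 17830444, both intronic, and Mir125a at 17830812 to 17830879, exonic). miR-99b-5p stood at 195, 755, 987 and 2497 ppm in HSC, imDC, maDC and DCreg, let-7e-5p at 3606, 6943, 26478 and 51264, and miR-125a-5p at 45.4, 50.8, 108 and 423. In recounted reads the values in that order were 105, 531, 561 and 1377 for miR-99b-5p, 1852, 4279, 15921 and 32599 for let-7e-5p, and 25.2, 37.6, 65.2 and 245 for miR-125a-5p. The cluster was singled out after its values were seen. The order held under all scalings tried, with the smallest step, miR-125a-5p in imDC against HSC, at a log2 ratio of 0.16 with the total and 0.074 with median-of-ratios. No explanation was tested.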
